A study of Homo sapiens with 9 samples.

How the data were processed

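RNA sequencing of poly(A) RNA was deposited for 9 libraries of SH-SY5Y cells, an established human neuroblastoma line, in 3 groups of 3. Per the labels, 1 pool of cells carried Cas9 with a control guide and 1 pool each carried a guide against SNAI2, gRNA1 or gRNA2, and each pool was sampled in independent experiments. The p-values of single genes therefore measure the spread between libraries of 1 pool per group. Fisher's tests of gene lists, windows and regions take genes as the unit instead. Genes measured in the same libraries are not independent replicates, so these p-values can be too small.

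The authors deposited 3 tables, each a comparison of 2 groups. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.30, DESeq 1.10.1, R 2.15.3 and the build hg19, without saying which step each served. The aligner, the counting tool and the use of strand were not given in the sources used here, so reads of genes that overlap another gene are uncertain. In each deposited table the signal is mean coverage, the mean over libraries of counts divided by size factors, given per group and over both groups, with size factors set within that table. The deposited ratio is the second group's mean over the first group's, and the deposited log2 value is its log2, infinite where a group is at 0. The authors' p-value of each gene and its adjusted p-value follow, with a rank by p. Each deposited table lists only genes with an unadjusted p under 0.05, and the adjusted p-values imply that 31134, 30294 and 31949 genes were tested in the comparisons of control with gRNA1, control with gRNA2, and gRNA1 with gRNA2. In the table of control and gRNA1, 1 rank is absent, and that gene was not analysed here.

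Genes were called at the authors' adjusted p under 0.05. This rule and the gene lists were set before the data were examined, for tables that hold only a comparison.

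Because means carry up to 15 printed digits, the whole reads of each library were recovered. The size factors were searched for jointly, and each group mean was then matched to the whole-number triple that gives it within 4 units of the last digits. Means over 6000 were not searched. Of the means searched, 100%, 96.1% and 100% had 1 triple in control, gRNA1 and gRNA2, and 160 gRNA1 means had several, of which the triple with libraries within 2-fold of each other was chosen. Where a group mean stood in both tables, the triple was the same for 2112 of 2112, 590 of 590 and 1028 of 1028 genes. Random values were matched in 0%, 0% and 0.667% of trials, and on simulated data every recovered triple was right. Both groups were recovered for 2569, 4358 and 1533 of the listed genes, which is 87.5%, 91.2% and 84.0%. Libraries in a group are lettered a to c from the deepest, because the means do not say which replicate each is.

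The totals over recovered genes are 4783398, 4663513 and 4117834 reads in control, 24538712, 6860355 and 4155916 in gRNA1, and 11877695, 6651552 and 4357462 in gRNA2. They cover only listed genes, 4968 in control, 3504 in gRNA1 and 4928 in gRNA2, so they do not compare depth between groups, and whole-library depth is unknown. Means with SD were computed from recovered reads on 1 common scale, that of the table of control and gRNA2, joined through the shared control libraries. With 1 to 3 reads in a group, the ratio was taken over its pooled reads divided by the sum of its size factors, with a 95% Poisson counting interval, and bounds for groups at 0 use a floor of 3 reads over the group. They cover counting error only, since reads without molecular identifiers are not independent molecules.

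As an alternative chosen after the data were seen, limma 3.58.1 in R 4.3.3 was run with trend on log2 of normalised reads plus 1. The Benjamini-Hochberg adjustment ran over the number of genes the authors tested. The fits used only listed genes with recovered reads. Listing by p for the same grouping favours small spread within groups, so limma p-values can be too small. Tested on simulated data, limma called 86%, 90% and 100% of genes changed 1.5-, 2- and 4-fold in the comparison of control with gRNA1. The simulated genes were not chosen by p, so they cannot show this. Fits of count models, set in advance for tables of counts per library, were not run, since the tables used here hold group means. They were not run on the recovered reads either, which cover listed genes only. SNAI2 was also compared by a two-sided exact permutation test. Genes were placed in GENCODE 29 (GRCh38) by Ensembl identifier, which placed 98.0%, 98.0% and 98.2% of the listed genes, and GC content was taken over exons.

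Named genes followed a rule set in advance. SNAI2 was always named. In each comparison with control, the rule takes the 8 highest and 8 lowest called genes with a symbol, a mean of at least 50 and both groups above 0. It also takes the 10 highest and 10 lowest shared by both guides, ranked by the smaller change, the 5 highest and 5 lowest between the guides, and up to 4 called members per list. Some genes that the rule takes are left out of the text but stay in every count. A gene named outside it is said to be chosen after its values were seen.

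The 33 gene lists cover regulators and structural genes of epithelial and mesenchymal states, neuroblastoma, neurons, neural crest, signalling, stress and metabolism, with markers of other cell types. Each list's called members, higher and lower, were compared with all other called genes by Fisher's exact test, two-sided, adjusted over the lists with at least 5 called members. The wording set in advance names all other listed genes and lists with at least 5 listed members. It was read as called genes for the main version, and the version over all listed genes is given as an alternative. Counts adjusted over the list alone use the authors' unadjusted p of the list's members.

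The overlap of the guides was set against independent lists and against a simulation in which unchanged groups shared the control libraries. The control libraries could not be divided into parts of at least 2. Windows of 10 Mb with at least 10 listed genes were compared with the rest of the listed genes. Alternatives were an adjusted p under 0.01, an absolute log2 of at least 1, a mean of at least 50, limma with pseudocounts of 1 and 0.1, each library left out, GC corrections by loess with a span of 0.75, fitted on genes not listed between the guides or on the listed genes themselves, and removal of the first 50 Mb of chromosome 2. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.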

Results

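Poly(A) RNA was sequenced from SH-SY5Y cells, an established human neuroblastoma line, carrying the nuclease Cas9 and a guide RNA. There were 3 groups of 3 libraries each, from a pool with a control guide and from pools with the SNAI2 guides gRNA1 and gRNA2. SNAI2 encodes a zinc-finger repressor of transcription of the Snail family. Recovered reads over the listed genes numbered 4783398, 4663513 and 4117834 in the control libraries, 24538712, 6860355 and 4155916 in those of gRNA1, and 11877695, 6651552 and 4357462 in those of gRNA2, summed over 4968, 3504 and 4928 genes, so they do not compare depth between groups. For listed genes with a mean of at least 500 (1561, 1526 and 2419 genes), the coefficient of variation within a group had a median of 7.89% in control, 7.58% in gRNA1 and 7.63% in gRNA2. Listing by p favours genes of small spread, so these values can be too low. Levels below are normalised reads, recovered per library and put on a common scale, as mean ± SD (n = 3). Log2 ratios and adjusted p-values are the authors', from their deposited tables, unless limma is named.

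SNAI2, the targeted gene, lies on chromosome 8 from 48917604 to 48921740 (GRCh38). Its mRNA stood at 267 ± 70.5 normalised reads in control, 451 ± 6.35 in gRNA1 and 271 ± 68.4 in gRNA2 (SD, n = 3), from 160 to 3541 reads per library. With gRNA1 it was 1.69-fold the control level, and the authors' deposited table gave log2 0.75 (adjusted p = 0.00502). With gRNA2 it was 1.01-fold the control level and was not listed in the authors' deposited table. Between the guides, the authors' deposited table gave log2 -0.74 for gRNA2 over gRNA1 (adjusted p = 0.0973). Exact permutation tests, two-sided, gave p = 0.1 for gRNA1 against control, 0.7 for gRNA2 against control and 0.1 between the guides, where 0.1 is the smallest p that 3 against 3 libraries allow. By limma the difference from control with gRNA1 was log2 0.79 (adjusted p = 0.0232), and it was no longer called without control library a (0.82) or without gRNA1 library a (0.79), b (0.80) or c (0.78). By limma the guides differed by log2 -0.77 (adjusted p = 0.00461), and this was not called without gRNA1 library a (-0.77) or b (-0.77). Limma ran only on listed genes, so its adjusted p-values can be too small. Indels at a Cas9 site need not lower the mRNA, so these levels do not measure the editing.

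**Figure D1:**
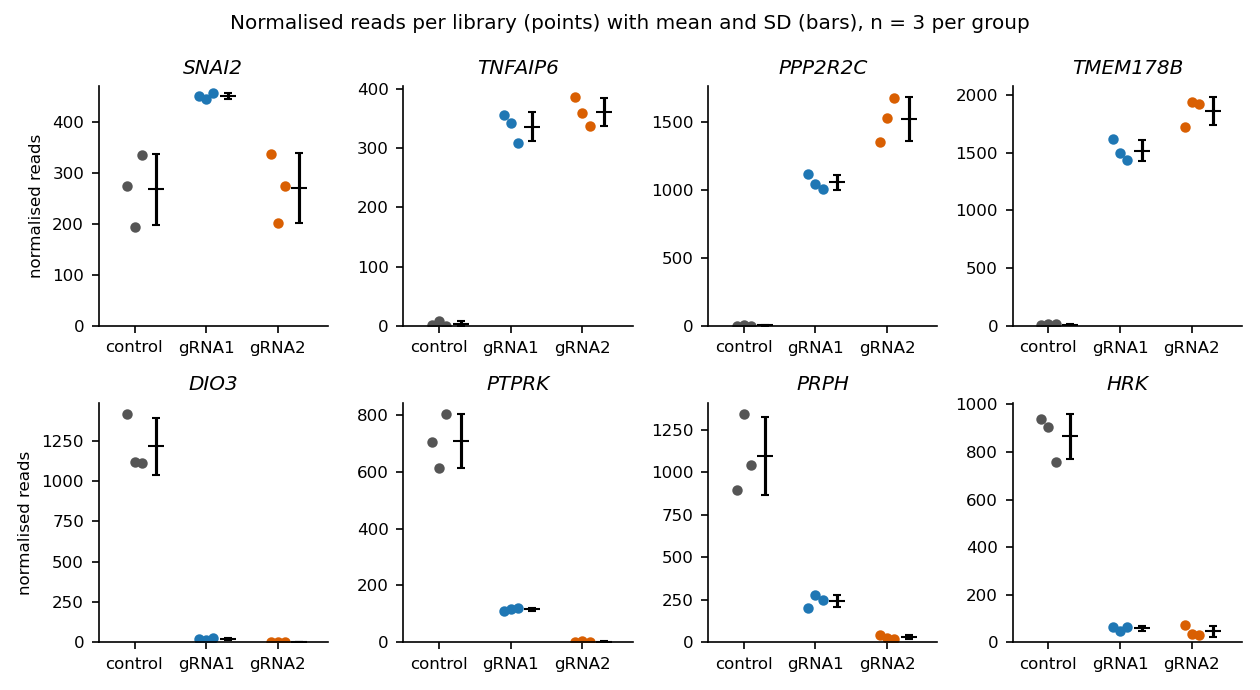
Normalised reads per library on the common scale for 8 genes (points, 3 libraries per group), with mean and SD as bars, on linear axes from 0. SNAI2 averaged 267 in control, 451 in gRNA1 and 271 in gRNA2, whereas DIO3 averaged 1215, 21.2 and 0.155.

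The comparison of control with gRNA1 asked which transcripts differ once SNAI2 is targeted. Several genes that gave few reads in control cells were among the most raised with gRNA1. TMEM178B, a membrane protein gene, went from 11.0 ± 5.66 to 1518 ± 92.0 normalised reads (SD, n = 3), and PPP2R2C, a regulatory subunit of protein phosphatase 2A, from 4.94 ± 4.12 to 1055 ± 55.6. In the other direction, DIO3, the deiodinase that inactivates thyroid hormone, fell from 1215 ± 175 to 21.2 ± 6.48, and HRK, a pro-apoptotic BH3-only gene, from 866 ± 94.7 to 59.5 ± 11.0. DIO3 lies on chromosome 14 from 101561351 to 101563452 and TMEM178B on chromosome 7 from 141074232 to 141480380 (GRCh38).

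The authors' deposited table called 1401 of the 31134 genes tested at adjusted p under 0.05, with 983 higher with gRNA1 and 418 lower. Of these, 717 changed at least 2-fold and 162 at least 10-fold, 156 of the latter higher and 6 lower. Several of the highest genes had 1 to 3 control reads in all, so their ratios are given over the pooled reads of the control libraries, with 95% Poisson intervals. The ratio was 415 (74.5 to 16402) for POU4F2, a transcription factor of sensory and retinal neurons, 340 (116 to 1649) for SLC6A11, a GABA transporter, and 258 (71.3 to 2128) for SERPINA5, a serpin whose exons overlap those of SERPINA4. It was 193 (34.6 to 7606) for C22orf34, 126 (43.2 to 613) for CACNG2, an auxiliary subunit of AMPA receptors, and 121 (33.5 to 998) for SYT13, a synaptotagmin. The authors' deposited table gave log2 7.11 for TMEM178B (adjusted p = 3.17e-227) and 7.74 for PPP2R2C (adjusted p = 8.71e-186). Among the lowest genes, DIO3OS, a transcript beside DIO3 on the other strand, fell from 546 ± 39.2 to 13.1 ± 3.35 normalised reads (SD, n = 3), HTR3A, a serotonin receptor channel, from 207 ± 103 to 13.9 ± 5.28, and IGDCC3 from 539 ± 19.3 to 39.2 ± 13.4. SUSD2 fell from 294 ± 116 to 35.5 ± 7.67, IGF2-AS, which overlaps IGF2 on the other strand, from 238 ± 44.7 to 37.1 ± 9.71, and the receptor phosphatase PTPRK from 706 ± 94.8 to 116 ± 4.24. In the authors' deposited table, the log2 ratio was -5.84 for DIO3 (adjusted p = 4.51e-45), -3.86 for HRK (adjusted p = 2.42e-43) and -3.89 for HTR3A (adjusted p = 0.0266). Without gRNA1 library a, which had 5.91 times the reads of library c, limma called 1044 genes, and without library c 1014, against 1605 with all libraries. Among all listed genes, the share higher with gRNA1 was 71.1% in the lowest of 5 bins by GC content and 48.0% in the highest.

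Genes of the mesenchymal cytoskeleton and adhesion fell as a group with gRNA1 when tested over called genes, but did not pass over all listed genes. All 5 called members were lower and 0 higher (Fisher's exact test against other called genes, two-sided, adjusted p = 0.0349; 0.0557 over all listed genes), and 5 were called when adjusted over the list alone. With calls at adjusted p under 0.01 or with an absolute log2 of at least 1, under 5 members were left and the list was not tested. CD44, the hyaluronan receptor, fell from 239 ± 56.0 to 88.6 ± 12.0 normalised reads (SD, n = 3), fibronectin (FN1) from 4702 ± 780 to 2387 ± 144 and the matrix protein gene SPARC from 5754 ± 946 to 3149 ± 80.5, while tropomyosin 1 (TPM1) had log2 -0.97 in the authors' deposited table. Of the synaptic vesicle and release genes, 14 were higher and 0 lower (adjusted p = 0.0725; 0.0370 over all listed genes), with 19 called when adjusted over the list alone, 18 higher and 1 lower. CPLX2 and CPLX1, complexins that act in vesicle fusion, rose from 387 ± 152 to 3153 ± 149 and from 106 ± 25.4 to 784 ± 89.5, and the synapsin SYN1 rose from 179 ± 69.7 to 839 ± 53.4. Of the neuronal cytoskeleton and maturation genes, 15 were higher and 2 lower (adjusted p = 0.218), with 18 called when adjusted over the list alone. In the authors' deposited table, doublecortin (DCX) had log2 2.88, the neurofilament gene NEFM 2.51 (adjusted p = 5.59e-118) and ELAVL2, a neuronal RNA-binding protein gene, 2.48, while PRPH, the intermediate filament peripherin, had -2.17 (adjusted p = 7.3e-06).

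Extracellular matrix genes were 4 higher and 8 lower with gRNA1 (Fisher's exact test, two-sided, adjusted p = 0.0666), with 15 called when adjusted over the list alone. Over all listed genes they were more often lower than other genes, 8 higher and 17 lower (adjusted p = 0.0420 by the same test). SERPINE2, a protease inhibitor, fell from 810 ± 101 to 227 ± 8.07 normalised reads (SD, n = 3), NID2, a basement membrane gene, from 525 ± 132 to 150 ± 5.54 and the metalloproteinase inhibitor TIMP1 from 1409 ± 70.8 to 547 ± 73.8, while the collagen gene COL1A2 rose from 61.3 ± 21.2 to 188 ± 18.4. Axon guidance genes were 3 higher and 6 lower (adjusted p = 0.0909), with 12 called when adjusted over the list alone; the netrin receptor gene UNC5A rose from 27.7 ± 15.9 to 217 ± 13.1 and the semaphorin co-receptor gene NRP2 fell from 176 ± 54.3 to 32.1 ± 2.33. Of the adrenergic neuroblastoma transcription factors, 5 were higher and 6 lower (adjusted p = 0.205), with 13 called when adjusted over the list alone. DACH1 fell from 2216 ± 129 to 587 ± 16.5, and SIX3 rose from 457 ± 12.9 to 1310 ± 99.7. SIX3 lies in the first 50 Mb of chromosome 2, where 148 of 152 listed genes were higher with gRNA1. The mesenchymal neuroblastoma transcription factors had 3 called members, SNAI2 higher and 2 lower, too few for the list test. When adjusted over the list alone, 6 were called, 3 higher and 3 lower, and of all listed members 4 were higher and 3 lower. YAP1 fell from 1637 ± 254 to 715 ± 59.0 and TBX18 from 1058 ± 148 to 513 ± 49.6. SNAI1, a relative of SNAI2, had log2 -1.40 in the authors' deposited table (adjusted p = 7.53e-12). Retinoic acid genes were 4 higher and 3 lower (adjusted p = 0.540), with 11 called when adjusted over the list alone; the carrier gene CRABP2 fell from 623 ± 142 to 161 ± 15.9 and ALDH1A3, which makes retinoic acid, from 2419 ± 315 to 1248 ± 87.9. Catecholamine genes were 5 higher and 2 lower (adjusted p = 1.0), with 7 called when adjusted over the list alone, and MAOA, which breaks down monoamines, fell from 1479 ± 270 to 558 ± 14.1. Targets of p53 were 6 higher and 0 lower (adjusted p = 0.256), with 7 called when adjusted over the list alone, 6 higher and 1 lower.

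**Figure D2:**
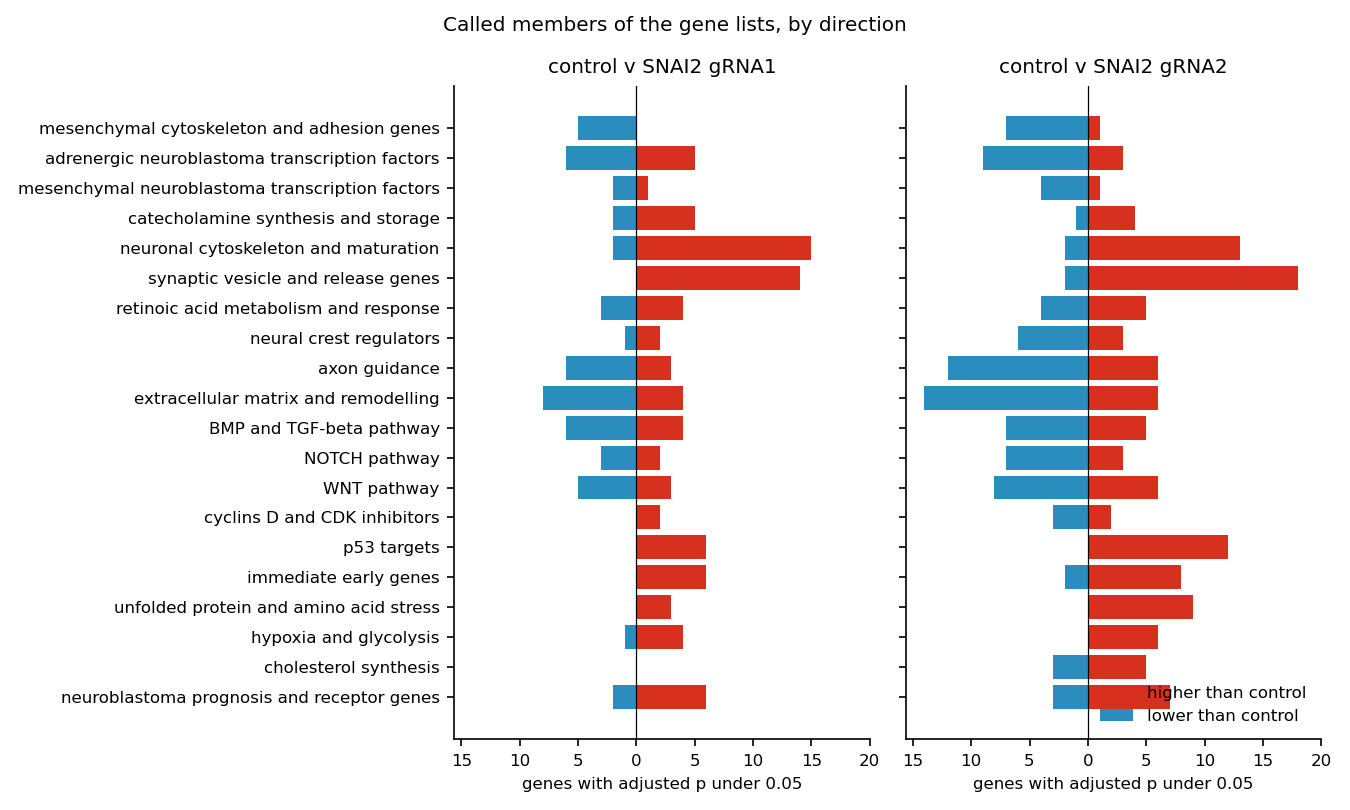
Number of called members (x axis, genes with the authors' adjusted p under 0.05) of each list with at least 5 called members in either comparison, red to the right for higher than control and blue to the left for lower. Synaptic vesicle genes were 14 higher and 0 lower with gRNA1 and 18 higher and 2 lower with gRNA2.

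The comparison of control with gRNA2 put the same question to the pool with the second guide. Transcripts of SERPINA5, SLC6A11, PPP2R2C and TMEM178B, near absent from control cells, were again among the highest, and several transcripts well above background in control nearly vanished. PPP2R2C rose from 4.94 ± 4.12 to 1518 ± 161 normalised reads (SD, n = 3) and TMEM178B from 11.0 ± 5.66 to 1859 ± 120. PTPRK fell from 706 ± 94.8 to 1.89 ± 1.71, BCHE, which encodes butyrylcholinesterase, from 946 ± 165 to 8.97 ± 4.81 and MOXD1, a monooxygenase gene, from 568 ± 84.8 to 9.09 ± 6.73. DIO3 was left with 1 read in 3 libraries, a control level 5025-fold that of the pooled gRNA2 libraries (95% Poisson interval 902 to 198490.0), or 7832-fold as a ratio of the means over libraries.

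The authors' deposited table called 2726 of the 30294 genes tested, with 1535 higher with gRNA2 and 1191 lower. Of these, 1211 changed at least 2-fold and 267 at least 10-fold, 175 of the latter higher and 92 lower. For genes with 1 to 3 control reads, the ratio over the pooled control reads was 746 (95% Poisson interval 206 to 6156) for SERPINA5, 633 (114 to 25007) for C22orf34, 620 (111 to 24503) for POU4F2, 459 (157 to 2224) for SLC6A11 and 149 (51.1 to 724) for CACNG2. It was 372 (66.8 to 14710.0) for MGST1, a microsomal glutathione transferase. The control level was 284-fold that of the pooled gRNA2 libraries (78.6 to 2346) for RP11-572C15.6, which had 2 reads there, or 443-fold as a ratio of the means over libraries. DIO3OS fell from 546 ± 39.2 to 2.54 ± 2.56 normalised reads (SD, n = 3) and PRRG1, a membrane protein gene, from 204 ± 31.5 to 3.64 ± 2.06. The authors' deposited table gave log2 -12.94 for DIO3 (adjusted p = 1.17e-106), -8.55 for PTPRK (adjusted p = 5.02e-95) and -6.72 for BCHE. PTPRK lies on chromosome 6 from 127968779 to 128520674 and BCHE on chromosome 3 from 165772904 to 165837472 (GRCh38). Among all listed genes, the share higher with gRNA2 was 28.5% in the lowest of 5 bins by GC content and 67.2% in the highest. Limma called 2899 genes with all libraries, 1922 without control library a and 1787 without gRNA2 library c.

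Synaptic vesicle and release genes rose as a group with gRNA2, 18 higher and 2 lower (Fisher's exact test, two-sided, adjusted p = 0.0230), with 21 called when adjusted over the list alone. The lists were not matched on GC content, which moved with the direction as given above, so its part in the gRNA2 list results was not tested. CPLX2 rose from 387 ± 152 to 5523 ± 981 normalised reads (SD, n = 3), CPLX1 from 106 ± 25.4 to 1103 ± 285 and SYN1 from 179 ± 69.7 to 931 ± 221. Targets of p53 also rose as a group, 12 higher and 0 lower (adjusted p = 0.0230), with 15 called when adjusted over the list alone, 14 higher and 1 lower. With an absolute log2 of at least 1, under 5 members were left and the list was not tested. CDKN1A, the cell-cycle inhibitor p21, rose from 1855 ± 61.4 to 5123 ± 1483 (authors' deposited table log2 1.47). The death receptor gene TNFRSF10B rose from 1304 ± 87.2 to 3766 ± 445 and the receptor gene EDA2R from 80.9 ± 11.9 to 406 ± 64.9. BBC3, the pro-apoptotic gene PUMA, had log2 0.88 in the authors' deposited table. Genes of the unfolded protein and amino acid stress responses rose, 9 higher and 0 lower (adjusted p = 0.0414), with 10 called when adjusted over the list alone. Without the first 50 Mb of chromosome 2, where PDIA6 lies, that group gave an adjusted p of 0.0597, and with calls at adjusted p under 0.01 it gave 0.122, while with an absolute log2 of at least 1 under 5 members were left and it was not tested. In the authors' deposited table, VLDLR had log2 1.41, DDIT4 1.19, SESN2 0.87 and CHAC1 0.82. By limma SESN2 was not called without gRNA2 library c (0.74), nor CHAC1 without control library a (0.86) or c (0.69) or gRNA2 library a (0.79) or c (0.68).

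Neuronal cytoskeleton and maturation genes were 13 higher and 2 lower with gRNA2 (adjusted p = 0.0831; 0.00771 over all listed genes), with 22 called when adjusted over the list alone. In the authors' deposited table, NEFM had log2 3.36 (adjusted p = 6.67e-19), DCX 2.55, NGFR, the low-affinity neurotrophin receptor, -2.98 and PRPH -5.09 (adjusted p = 2.42e-26). Extracellular matrix genes were 6 higher and 14 lower (adjusted p = 0.0831), with 22 called when adjusted over the list alone; SERPINE2 fell from 810 ± 101 to 39.2 ± 18.9 normalised reads (SD, n = 3) and TIMP1 from 1409 ± 70.8 to 93.1 ± 42.6. Mesenchymal cytoskeleton and adhesion genes were 1 higher and 7 lower (adjusted p = 0.0831), with 8 called when adjusted over the list alone, and CD44 fell to 64.0 ± 16.6. Mesenchymal neuroblastoma transcription factors were 1 higher and 4 lower (adjusted p = 0.310), with 6 called when adjusted over the list alone; YAP1 fell to 177 ± 58.4 and TBX18 to 90.1 ± 40.4. Adrenergic transcription factors were 3 higher and 9 lower (adjusted p = 0.0974), with 14 called when adjusted over the list alone, and DACH1 fell to 229 ± 19.9. Axon guidance genes were 6 higher and 12 lower (adjusted p = 0.128), with 21 called when adjusted over the list alone, and UNC5A rose to 638 ± 201. Retinoic acid genes were 5 higher and 4 lower (adjusted p = 1.0), with 11 called when adjusted over the list alone; CRABP2 fell to 67.6 ± 11.2, while DHRS2, a short-chain dehydrogenase gene, rose from 35.7 ± 20.2 to 241 ± 29.3. Catecholamine genes were 4 higher and 1 lower (adjusted p = 0.524), with 5 called when adjusted over the list alone, and neural crest regulators were 3 higher and 6 lower (adjusted p = 0.310), with 10 called when adjusted over the list alone. SNAI1 had log2 -2.02 in the authors' deposited table (adjusted p = 1.51e-25).

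The overlap of both comparisons asked whether the guides gave the same changes. They shared 1243 called genes, of which 1242 had the same direction, 854 higher and 388 lower, where independent lists out of 30294 genes would share 49.8 and 16.4. Shared genes made up 86.9% of the higher and 92.8% of the lower calls of gRNA1, and 55.6% and 32.6% of those of gRNA2. In a simulation of unchanged groups with the same control libraries, a mean of 46.5 of 4496 genes reached an unadjusted p under 0.05 in both comparisons, 99.96% of them with the same sign, and 0 were called in both by limma. Among genes past that unadjusted p in both comparisons, the same direction is thus what shared controls alone give. For these genes it is no measure of the guides giving the same changes. With 0 simulated genes called in both, the simulation cannot show this for the called genes. Part of the overlap may come from the shared controls, and how large a part was not determined. The simulation holds no difference between pools, so it cannot show what a control pool unlike both guide pools would give. Among the highest shared genes, TNFAIP6, a hyaluronan-binding protein gene, stood at 336 ± 24.5 normalised reads with gRNA1 and 361 ± 24.1 with gRNA2 against 3.62 ± 4.38 in control (SD, n = 3). CELF2, an RNA-binding protein gene, stood at 136 ± 16.0 and 119 ± 21.4 against 1.33 ± 1.39. Among the lowest, HRK stood at 59.5 ± 11.0 and 46.5 ± 22.7 against 866 ± 94.7, IGDCC3 at 39.2 ± 13.4 and 17.9 ± 5.81 against 539 ± 19.3, and NRP2 at 32.1 ± 2.33 and 15.7 ± 7.02 against 176 ± 54.3. Of 1227 shared genes with finite ratios, 993 (80.9%) had the larger change with gRNA2, 340 of the 386 lower and 653 of the 841 higher. These are point values, and the median ratio of the log2 changes, gRNA2 over gRNA1, was 1.42 for lower and 1.13 for higher genes. Of the 1242 shared genes, 147 were called between the guides. All 74 lower genes among these were further lower in gRNA2, and 57 of the 73 higher genes were further higher. The 1 gene called in opposite directions was OSMR, the oncostatin M receptor, with 58.5 ± 18.6 in control, 125 ± 20.3 in gRNA1 and 6.21 ± 3.64 in gRNA2. In the authors' deposited tables its log2 was 1.09 with gRNA1 (adjusted p = 0.0117) and -3.24 with gRNA2 (adjusted p = 7.3e-06); by limma the rise with gRNA1 was not called without control library a or without any 1 of the gRNA1 libraries, and gave adjusted p = 0.0649 with a pseudocount of 0.1.

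**Figure D3:**
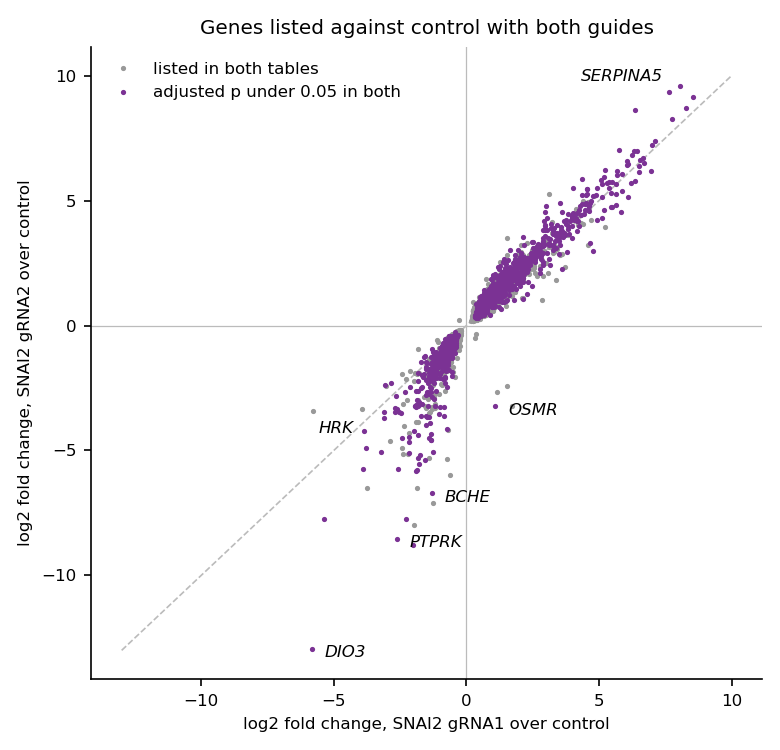
Log2 fold change over control with gRNA1 (x axis) and with gRNA2 (y axis), 1 point per gene listed in both of the authors' deposited tables with finite values, purple for genes called in both; the dashed line marks equal change. Of 2360 genes listed in both, 2353 (99.7%) had the same sign. In simulated unchanged groups with shared controls, a mean of 46.5 of 4496 genes reached an unadjusted p under 0.05 in both by limma. Of these, 99.96% had the same sign. DIO3 and PTPRK lie furthest below the line among the genes labelled in the plot.

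The comparison of gRNA1 with gRNA2 asked where both pools, aimed at the same gene, differ. The transcripts that nearly vanished with gRNA2 set them apart, since gRNA1 cells kept part of them. MOXD1 stood at 373 ± 36.3 normalised reads in gRNA1 and 9.09 ± 6.73 in gRNA2 (SD, n = 3), BCHE at 388 ± 22.4 and 8.97 ± 4.81, PTPRK at 116 ± 4.24 and 1.89 ± 1.71, and PRPH at 243 ± 37.0 and 32.1 ± 12.3. In the other direction, CHST15, a sulfotransferase gene, stood at 97.8 ± 3.52 in gRNA1 and 473 ± 60.1 in gRNA2, MGST1 at 32.6 ± 8.73 and 156 ± 20.7, and SERPINA5 at 215 ± 6.30 and 623 ± 80.2.

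The authors' deposited table called 333 of the 31949 genes tested, 106 higher in gRNA2 and 227 lower. Of these, 164 differed at least 2-fold and 34 at least 10-fold, 1 of the latter higher in gRNA2 and 33 lower, and 305 were also called in a comparison with control. Its log2 was -7.10 for DIO3, -5.94 for PTPRK, -5.43 for BCHE, -5.36 for MOXD1, 2.27 for CHST15 and 2.26 for MGST1. BAGE2 and TPTE, members of families with many near-identical copies, had 0 control reads; with a floor of 3 reads over the group, BAGE2 was at least 47.0-fold and TPTE at least 35.9-fold above control in gRNA2. GLT1D1, also at 0 in control, was at least 48.6-fold above it in gRNA2 with the same floor. Among all listed genes, the share higher in gRNA2 was 3.66% in the lowest of 5 bins by GC content and 84.5% in the highest. Without gRNA1 library a limma called 303 genes, without b 382 and without c 337, against 604 with all libraries.

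Of the lists, 4 had at least 5 called members between the guides and 0 passed the two-sided Fisher's exact test over called genes. Adrenergic transcription factors were 1 higher and 5 lower in gRNA2 (adjusted p = 0.912), with 8 called when adjusted over the list alone and DACH1 at 587 ± 16.5 and 229 ± 19.9 normalised reads (SD, n = 3). Retinoic acid genes were 2 higher and 3 lower (adjusted p = 0.912), with 8 called when adjusted over the list alone and CRABP2 at 161 ± 15.9 and 67.6 ± 11.2. Extracellular matrix genes were 3 higher and 4 lower (adjusted p = 0.912), with 11 called when adjusted over the list alone and TIMP1 at 547 ± 73.8 and 93.1 ± 42.6, and WNT pathway genes were 2 higher and 4 lower (adjusted p = 1.0), with 7 called when adjusted over the list alone. YAP1, a co-activator of the Hippo pathway, stood at 715 ± 59.0 and 177 ± 58.4, and TBX18 at 513 ± 49.6 and 90.1 ± 40.4. Over all listed genes, p53 targets (6 higher, 0 lower; adjusted p = 0.0261), hypoxia and glycolysis genes (8 and 0; 0.00610), cytoplasmic ribosomal proteins (10 and 0; 0.00320) and mitochondrially encoded transcripts (9 and 0; 0.00383) were more often higher in gRNA2, where GC content moved with the direction as given above.

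Genes of the first 50 Mb of chromosome 2 (GRCh38) were mostly higher with both guides, a region chosen after its values were seen. Fisher's tests of the region take its genes as independent, which neighbouring genes of the same libraries need not be. Their p-values can be too small for both reasons. With gRNA1, 148 of 152 listed genes there were higher (97.4%, against 59.0% elsewhere; Fisher's exact test, two-sided, p = 1.13e-27), with a median log2 of 0.53. With gRNA2, 186 of 193 were higher (96.4%, against 51.2% elsewhere; Fisher's exact p = 3.07e-43), with a median log2 of 0.59. The region held 101 and 154 of the higher calls, or 10.3% and 10.0%, of which 22 and 32 were at least 2-fold. ALK, a receptor tyrosine kinase gene on chromosome 2 from 29192774 to 29921566, rose from 540 ± 73.8 normalised reads to 3252 ± 185 with gRNA1 and 3170 ± 292 with gRNA2 (SD, n = 3), well above that median. MYCN, in the same region, was lower, with log2 -0.91 and -1.05 in the authors' deposited tables. By limma MYCN was not called with gRNA1 without control library c (-0.78) or gRNA1 library a (-0.79), b (-0.93) or c (-0.98), nor with gRNA2 without control library c (-0.92) or gRNA2 library b (-0.97). Between the guides, 35 of 40 listed genes of the region were higher in gRNA2 than in gRNA1 (87.5%, against 41.2% elsewhere and 58.0% of GC-matched genes elsewhere; Fisher's exact test against all elsewhere, two-sided, p = 2.74e-09), with a median log2 of 0.32, and 2 of them were called. On the rest of chromosome 2, 57.5% and 43.8% of the listed genes were higher than in control. In a scan of windows of 10 Mb, 8 of 120 windows passed an adjusted p under 0.05 with gRNA1, 25 of 207 with gRNA2 and 15 of 43 between the guides, of which 4, 5 and 1 lay in this region. The lowest adjusted p in each comparison with control was that of the window from 20000001 to 30000000 on chromosome 2 (1.05e-08 and 7.88e-17).

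**Figure D4:**
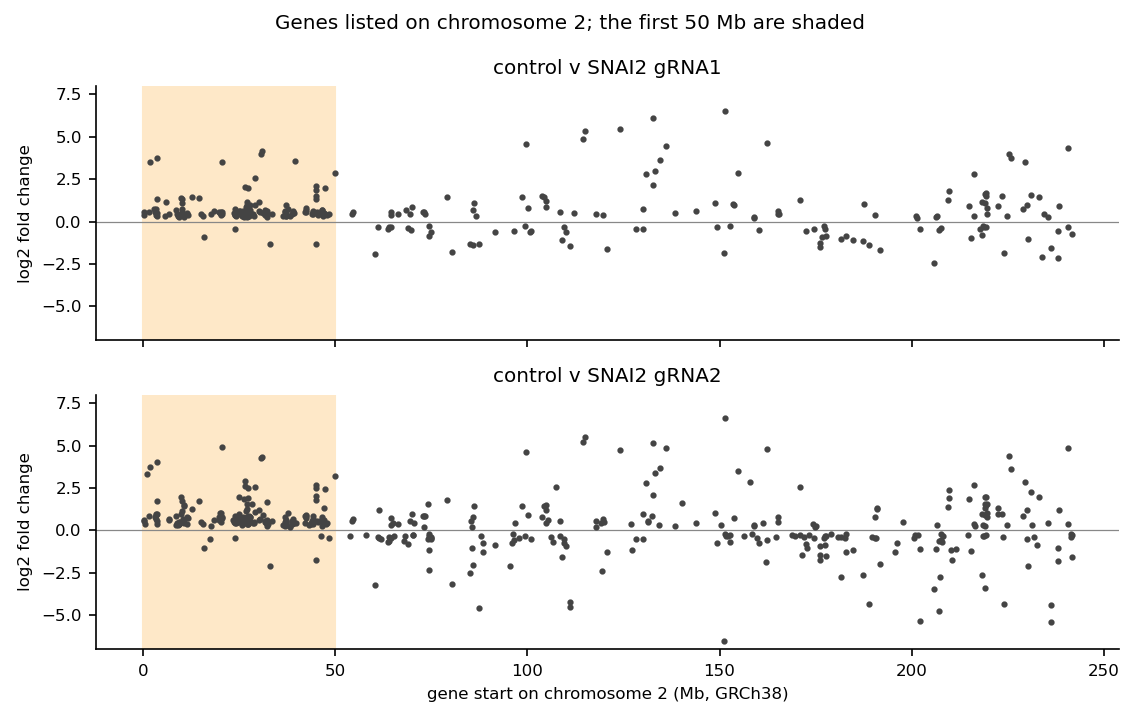
Log2 fold change over control (y axis) of each gene listed on chromosome 2 with a finite value, by its start in Mb (x axis, GRCh38), for gRNA1 (top) and gRNA2 (bottom), with the first 50 Mb shaded. In the shaded part, 148 of 152 and 186 of 193 listed genes were above 0.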

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

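Among the tests in this part, those of a copy-number difference on chromosome 2, of a fixed share of control-like cells and of the GC trend of the listed genes themselves were chosen only after the result was seen, and all limma fits and their splits rest on an analysis chosen after the data were seen.

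The results below differed between the guides by the authors' own test of gRNA2 against gRNA1 at adjusted p under 0.05, with values as log2 of gRNA2 over gRNA1 from the authors' deposited table. Among transcripts largely lost with gRNA2, the values were -7.10 for DIO3, -6.78 for RP11-572C15.6, -5.94 for PTPRK, -5.43 for BCHE, -5.36 for MOXD1, -4.61 for FRRS1, a reductase gene, -4.33 for OSMR, -3.92 for PRRG1 and -2.92 for PRPH. DIO3 had 1 read and RP11-572C15.6 had 2 reads in gRNA2, so the size and order of their values are uncertain. Named members of the matrix and mesenchymal lists, which did not pass a list test between the guides, gave -2.98 for COL3A1, -2.56 for TIMP1, -2.53 for SERPINE2, -2.51 for TBX18, -2.01 for YAP1 and 1.48 for S100A4, a calcium-binding protein gene. Signalling and guidance genes gave -1.59 for SEMA3F, -1.34 for TGFB3, -1.18 for TCF7L1, -0.78 for INHBA and 0.95 for LEF1. Transcription factors gave -1.36 for DACH1 and -0.95 for INSM2, and immediate early genes gave -1.61 for NR4A3, -0.95 for CYR61 and 0.82 for MYC. Retinoic acid genes gave -1.25 for CRABP2, -0.59 for ALDH1A3 and 0.46 for STRA6. Neuronal and secretory genes gave -0.89 for ELAVL2 and -0.51 for SCG2, and the sterol transporter gene STARD4 gave -0.68. Stress and glycolysis genes gave 1.01 for ADM, 0.74 for VLDLR, 0.58 for DDIT4, 0.44 for TNFRSF10B and 0.44 for PFKP. The highest values were 4.14 for BAGE2, 2.38 for TPTE, 2.27 for CHST15, 2.26 for MGST1, 1.91 for GLT1D1 and 1.53 for SERPINA5. By limma, ADM was not called without gRNA1 library a, GLT1D1 without gRNA1 library b, PFKP without gRNA1 library a or c, and TNFRSF10B without any 1 of the gRNA1 libraries or gRNA2 library a.

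The first pattern weighed was the rise of nearly all listed genes in the first 50 Mb of chromosome 2 with both guides. GC content as the only cause is argued against, since of GC-matched genes elsewhere 62.1% were higher with gRNA1 and 48.5% with gRNA2. The share in the region lay at least 35.3 percentage points above these. The region was chosen for its high share, so the size of this gap can be too large. A copy-number difference of this segment between the control pool and both guide pools stays open: the share of its protein-coding genes listed as higher was at least 6.40 times that elsewhere, but the region was chosen for this and the value gives no support. Copy number was not measured, and 35 of 40 listed genes there were higher in gRNA2 than in gRNA1, against 58.0% of GC-matched genes elsewhere, with 2 of the 40 called. Whether the difference comes from the SNAI2 guides or from the pools cannot be told apart, because the design has 1 control pool.

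The second pattern weighed was that genes of higher GC content tended to be higher in gRNA2 than in gRNA1. A GC trend as the whole cause of the calls stays open. A GC trend of each library was fitted on 1315 genes listed against control with both guides but not between the guides, with guide means of at least 50. Of the limma calls, 85.3% (511 of 599) stayed called after this trend was removed, but Spearman's rho over 1503 genes moved only from 0.385 to 0.346. Genes chosen for no listed difference between the guides can understate the trend, so this correction can remove too little of it. With the trend of the listed genes themselves removed, which brought rho to 0.0518 and can also take out real changes, 46.9% (281 of 599) stayed called in the same direction. Whether the trend may come from 1 library alone stays open: over 1315 genes not listed between the guides, which are not independent replicates, Spearman's rho of 0.208 (Pearson's r 0.199, permutation p = 1e-05, the smallest 100000 permutations can give) became -0.023 without gRNA1 library a but also 0.0674 without gRNA2 library c. The deviations of these libraries followed GC with a rho of -0.735 and 0.407, and that of gRNA1 library b with 0.438. A biological difference between the guides stays open, as untested.

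The third pattern weighed was that genes nearly lost with gRNA2 kept part of their level with gRNA1. With a control mean of at least 50 required, 12 genes were under 2% of control in gRNA2, against 1 gene under 2% in gRNA1. Over the 12 genes, the median share of the control level was 1.03% in gRNA2 and 24.4% in gRNA1. A fixed share of control-like cells in the gRNA1 pool is argued against as the only source of the levels left. The share left ran from 1.80% for DIO3 (95% Poisson interval 1.58 to 2.04) to 65.1% for MOXD1 (63.2 to 67.1), a ratio of 36.2. These intervals cover counting error only. A small fixed share of such cells beside other differences stays open. The share left in gRNA1 did not rest on its deeper libraries, since the shallowest gRNA1 library alone had a median share of 26.0%. This is 25.4 times the share in gRNA2. The ratio cannot decide on deeper sequencing as the cause, since the shares are normalised for depth and the level in gRNA2 was set by the choice of genes. By the size factors of the table of both guides, the shallowest gRNA1 library (0.704) was deeper than 2 of the gRNA2 libraries but shallower than gRNA2 library a (1.14). In gRNA2 library a the median share was 0.986%, a comparison added after the result was seen. A mixture of clones with different changes, and different edits by the guides, stay open as untested.

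For the numbers of genes called by limma, 3 against 3 libraries give 10 splits, of which 1, the real one, called as many in each comparison, and these are too few for a share under 0.05. The real split called 1605 genes for control against gRNA1, 2899 for control against gRNA2 and 604 between the guides, and the highest other split called 0, 0 and 3. These fits ran only on the 2569, 4358 and 1533 genes with recovered reads that the authors list for the real grouping, which keeps the other splits low by construction.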

How the results depend on the processing

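All fits by limma, each fit without 1 library, the GC corrections and the removal of the first 50 Mb of chromosome 2 were chosen after seeing the data. The list test over all listed genes follows the wording set in advance, which the main version read as called genes. No paired analysis was possible because the recovered libraries of a group carry no replicate numbers. Count models with other normalisations or count filters were not run, since the tables used here hold group means of genes with an unadjusted p under 0.05.

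The counts of called genes stayed within 1.5 times their value at adjusted p under 0.01 (1055, 2059, 236 and 937 for gRNA1, gRNA2, between the guides and shared), with a mean of at least 50 (1280, 2421, 304 and 1130), and without the region of chromosome 2 (1298, 2570, 331 and 1142). Requiring an absolute log2 of at least 1 left 717, 1211, 164 and 636, which follows from the added criterion. Limma called 604 genes between the guides with a pseudocount of 1 and 410 with 0.1, against 333 by the authors. For gRNA1 and gRNA2 it called 1605 and 2899 with a pseudocount of 1 and 1434 and 2626 with 0.1. It ran only on listed genes, which can make its p-values too small and its counts too high. Over the 1503 genes between the guides with GC content, it called 599 before and 608 after a GC trend fitted on other genes was removed, and 360 after that of the listed genes themselves was removed; the cause was not tested. With a pseudocount of 1 its calls held 1216 of the 1224 genes the authors called with reads recovered for gRNA1, 2361 of 2468 for gRNA2 and 295 of 297 between the guides. Leaving out 1 library, limma called from 1014 (without gRNA1 library c) to 1637 (without control library b) genes for gRNA1, from 1787 (without gRNA2 library c) to 2493 (without gRNA2 library a) for gRNA2, and from 303 (without gRNA1 library a) to 698 (without gRNA2 library b; 644 without library a) between the guides, where fewer libraries also lower the power.

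For SNAI2 with gRNA1, the limma value was log2 0.79 with a pseudocount of 1 and 0.79 with 0.1, and ran from 0.57 (without control library b) to 0.97 (without control library c). It lost its call without control library a (0.82) or gRNA1 library a (0.79), b (0.80) or c (0.78); the cause was not tested. Between the guides, the authors' test gave adjusted p = 0.0973 for SNAI2. Limma called it at log2 -0.77 with either pseudocount (adjusted p = 0.00461 and 0.0232), but limma p-values over listed genes can be too small. The limma value ran from -0.94 (without gRNA2 library a) to -0.57 (without gRNA2 library b), and the cause was not tested. SNAI2 was also called without gRNA1 library c (-0.76) and without gRNA2 library c (-0.79).

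The number of gene lists past the threshold for gRNA1 was 1, and became 2 over all listed genes, 0 at adjusted p under 0.01 and 2 with an absolute log2 of at least 1. For gRNA2 it was 3, and became 6 over all listed genes, 2 at adjusted p under 0.01, 2 with an absolute log2 of at least 1 and 2 without the region of chromosome 2. Between the guides it was 0, and became 4 over all listed genes. For these counts the cause was not tested. Of 260 called values of named genes with finite ratios, 229 had reads recovered. With a pseudocount of 1, limma kept all 229, and 206 were kept without any 1 library, while 0 turned direction. With a pseudocount of 0.1, OSMR with gRNA1 was not called (limma adjusted p = 0.0649). The 23 that lost their call in at least 1 fit without a library include SUSD2 with gRNA2 without gRNA2 library c (-2.23), MYCN with both guides, and CHAC1, SESN2 and S100A4 with gRNA2. Whole-library depth is unknown, and genes with an unadjusted p of 0.05 or more are not in the tables, so absence from a list does not show that a gene was unchanged.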

Other observations

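Signalling lists had many called members that went both ways. Of the BMP and TGF-beta genes, 4 were higher and 6 lower with gRNA1 (Fisher's exact test, two-sided, adjusted p = 0.185) and 5 higher and 7 lower with gRNA2 (adjusted p = 0.524), with 10 and 13 called when adjusted over the list alone. BMP7, a bone morphogenetic protein gene, rose from 40.8 ± 18.6 normalised reads in control to 637 ± 25.5 with gRNA1 and 853 ± 86.8 with gRNA2 (SD, n = 3), and the activin subunit gene INHBA from 360 ± 28.7 to 1243 ± 93.1 and 724 ± 112. WNT pathway genes were 3 higher and 5 lower with gRNA1 (adjusted p = 0.169) and 6 higher and 8 lower with gRNA2 (adjusted p = 0.524), with 10 and 16 called when adjusted over the list alone. In the authors' deposited tables the ligand gene WNT5A had log2 -1.73 and -2.51, and LEF1, a transcription factor of the pathway, had 1.01 and 1.96. NOTCH pathway genes were 2 higher and 3 lower (adjusted p = 0.256) and 3 higher and 7 lower (adjusted p = 0.230), with 8 and 11 called when adjusted over the list alone, and the receptor gene NOTCH3 fell from 5390.01 ± 83.4 to 2880.1 ± 350.5 and 2296 ± 256. Immediate early genes were 6 higher and 0 lower (adjusted p = 0.256) and 8 higher and 2 lower (adjusted p = 0.310), with 8 (7 higher, 1 lower) and 13 (9 higher, 4 lower) called when adjusted over the list alone; EGR1 rose from 339.5 ± 63.1 to 1427 ± 161 and 1436 ± 328, and ARC from 118 ± 10.6 to 545 ± 71.6 and 681 ± 44.4.

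Neuroblastoma prognosis and receptor genes were 6 higher and 2 lower with gRNA1 (adjusted p = 1.0) and 7 higher and 3 lower with gRNA2 (adjusted p = 0.621), with 10 and 12 called when adjusted over the list alone, and CHD5, a chromatin remodeller gene, rose from 33.5 ± 11.1 to 319 ± 28.8 and 274 ± 68.8 normalised reads (SD, n = 3). Hypoxia and glycolysis genes were 4 higher and 1 lower (adjusted p = 1.0) and 6 higher and 0 lower (adjusted p = 0.0974), with 5 (4 higher, 1 lower) and 8 (7 higher, 1 lower) called when adjusted over the list alone. Cyclins D and CDK inhibitors had 2 called members with gRNA1, both higher, and 2 higher and 3 lower with gRNA2 (adjusted p = 0.732), with 6 called for gRNA2 when adjusted over the list alone; CDKN2A, whose exons overlap those of CDKN2B-AS1, rose from 29.2 ± 7.41 to 245 ± 57.7 and 332 ± 39.4. Cholesterol synthesis genes had 0 called members by the authors' test with gRNA1, with 6 at an unadjusted p under 0.05, and 5 higher and 3 lower with gRNA2 (adjusted p = 1.0), with 9 called when adjusted over the list alone.

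The lists of epithelial adhesion genes, HOX genes, cell cycle and DNA replication, apoptosis regulators, interferon response, cytoplasmic ribosomal proteins, oxidative phosphorylation subunits, mitochondrially encoded transcripts, Schwann cell and glial markers, fibroblast and smooth muscle markers, and endothelial and blood cell markers had fewer than 5 called members in each comparison and were not tested over called genes, and the list of histones and mRNA decay had 0 by the authors' test, with 1 and 2 genes at an unadjusted p under 0.05 against control. Cell cycle genes were 1 higher and 0 lower with gRNA1 and 1 higher and 2 lower with gRNA2, apoptosis regulators 1 and 1 and then 2 and 2, and ribosomal proteins, oxidative phosphorylation subunits and mitochondrial transcripts 1 higher each with gRNA2. Unfolded protein genes were 3 higher and 0 lower and neural crest regulators 2 higher and 1 lower with gRNA1. Epithelial adhesion genes were 0 higher and 1 lower with gRNA1 and 1 higher and 2 lower with gRNA2, and the HOX list had HOXD10 lower with both, with log2 -1.23 and -1.45 in the authors' deposited tables. Of the Schwann cell and glial markers, 1 was higher and 2 lower with gRNA1, and 2 higher and 2 lower with gRNA2, with NGFR lower with both guides. Of the fibroblast and smooth muscle markers, 1 was higher and 1 lower with gRNA1, and 1 higher and 2 lower with gRNA2. COL1A2 was higher and COL3A1 lower with both guides, and COL1A1 was lower with gRNA2, with log2 -1.55 in the authors' deposited table. By limma COL1A2 with gRNA2 was not called without control library a (1.26) or b (1.31) or gRNA2 library a (1.18) or b (1.34). Among endothelial and blood cell markers, FLT1 was lower with gRNA2, with log2 -2.82, and in the interferon list 2 were lower with gRNA2, IFITM2 with log2 -3.51 among them, both in the authors' deposited table. Over all listed genes, cell cycle genes were 2 higher and 11 lower with gRNA2 (adjusted p = 0.0422) and cytoplasmic ribosomal proteins 10 higher and 0 lower (adjusted p = 0.0123). With gRNA2 the direction of listed genes moved with GC content, and its part in these 2 results was not tested.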
